A study of Danio rerio with 1140 samples.

How the data were processed

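The series holds 1140 GEO samples, each 1 sorted cell from gng8-GFP zebrafish larvae at 10 days. Per the series design, 22 fish were taken in 3 batches, with 384 wells planned for each. Per the labels, batch 1 filled plates 1 to 4, batch 2 plates 6 to 9, and the plates of batch 3 are not given. The tables hold 372 cells of batch 1 and 384 cells of each other batch. The replicate was the batch, given by the count table that each sample's description names, and cells were never counted as replicates. The 3 tables were taken to be the 3 batches of fish of the series design, but no label says which fish gave which cell. With the batch as a block, p-values of single genes measure how unevenly the classes differ from table to table. Some of that spread may be technical. Those of gene lists in camera, described below, compare the genes of a list with the other genes.

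The authors deposited a table of RSEM expected counts and a table of TPM for each batch. The expected counts were used, with 26986 genes and every cell column, and TPM were left out because they keep no depth. Per the submitters' processing notes, RSEM 1.2.28 and TopHat2 2.0.10 were used, with no role or order given for either. The genome build and gene annotation are not given in the sources used here, so gene names are those of the tables and no coordinates are printed. Expected counts were rounded to whole numbers after summing for the count models. 7 gene names occur on more than 1 line, and such genes were kept apart and not named. Smart-seq2 has no molecular tags, so PCR copies count as reads, and exact intervals and count floors cover counting error only.

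A cell was kept with at least 1000 genes at an expected count of 1 or more and at least 50000 counts. Wells whose profiles correlated above 0.9 were taken as 1 cell. 3 such pairs had correlations of 0.998, 0.989 and 0.981 and chi-square values per degree of freedom of 1.41, 1.75 and 1.13, against a median of 283 for 200 random pairs. In 2 pairs both wells passed the filter and were merged. In the third, one well had 47660 counts and failed. No doublet caller was run, because each well was sorted to hold 1 cell. An alternative left out the 2% of cells with most genes.

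For clusters, counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were taken over the batches and z-scored within each batch, and 30 principal components, 15 neighbours and Leiden resolution 1.0 were used. A cluster was named as a cell type outside the habenula only by the marker list with the highest mean log2 difference in it. At least 3 genes of that list had to have a log2 difference of at least 1. At least 1 gene of the list had to stand among the cluster's top 10 genes. Gates on single genes were set at 50 CPM, with 10 and 200 CPM as alternatives, and cells negative for slc5a7a or for tubb5 and sox4a had those genes under 5 CPM. A comparison needed at least 10 cells per class in at least 2 batches. Cells of the cluster named as another type were left out of the gates. A gate is a range of a measured level, not a cell type, and a gene below its gate may still be expressed.

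The planned test was edgeR (quasi-likelihood, robust) on the sum of counts per class and batch, with all classes of the gate in the fit, so that in the KCTD comparison cells with both genes or neither add to the estimate of spread, and with TMM scaling, filterByExpr, the batch as a block and Benjamini-Hochberg adjustment at 0.05. Standard errors of its log2 folds are the fold divided by the square root of F. Genes that define a gate were left out of the test of that gate. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, where at least 3 members were tested. Counts adjusted over a list alone cover all its tested members, those that passed over all genes included. There were 32 lists of 982 genes, 897 of them in the tables, covering transmitters, peptides, receptors, channels, guidance, transcription, signalling, cell state and other cell types. The thresholds, gates, lists, marker sets, planned comparisons and the other settings listed for them were fixed before the data were examined.

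Several choices were made after seeing the data. The planned test found few genes, so limma (trend and robust) was added on the class and batch means of log2(CPM + 1) of single cells. It used genes found in 10% of cells, 9413 of them, and that level was set once. Its differences mix how many cells express a gene with how much, and shrink folds of low genes. Cells have equal weight within a class and batch, and each mean counts alike whatever its number of cells. The comparisons on slc5a7a and on tubb5 with sox4a were added as well. A comparison of 26 cells positive for aoc1 or kiss1 was tried and dropped, because sums held as few as 3 cells. There edgeR called 0 of 16042 genes (2837 at unadjusted p under 0.05) and 0 of 9261 genes found in 10% of cells (907 unadjusted), and DESeq2 on those genes called 1468.

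Other fits were tried and not used for naming. On genes found in 10% of cells DESeq2 called 294 genes between the KCTD classes, 279 for slc5a7a and 2115 for tubb5 with sox4a. With adjustment over genes above 50 CPM only, edgeR called 1 of 3807 genes between the KCTD classes (321 unadjusted), and 0 of 3752 when only those classes were fitted (452 unadjusted). With cells of each batch shuffled between the KCTD classes in 8 draws, edgeR and limma each called 0 genes in every draw, while DESeq2 called 470 to 567 genes, median 494. For tubb5 with sox4a edgeR and limma likewise called 0 in each of 8 draws. DESeq2 counts are therefore printed only beside the others.

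The pairing comes from the design, since the classes of a batch are taken to come from the same pool of fish. Deviations of the paired classes from their class means correlated at 0.105, 0.091 and 0.153 for the KCTD classes, 0.208, 0.158 and 0.207 for slc5a7a, and 0.088 and 0.09 for tubb5 with sox4a.

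Genes were named by a rule. Those with adjusted p under 0.05, the same direction in all batches and at least 20 CPM in one class were ranked by difference. The 10 largest in each direction were named. Besides these, up to 4 members of each list with adjusted p under 0.05 were named by smallest p, without the other conditions. Names that are only identifiers were passed over. Genes outside that rule are given as values and were chosen after their values were seen.

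The tests were tested on simulated data built from the measured class sums and means. With edgeR, planted folds of 4, 16 and 64 were recovered for 1.49%, 13.4% and 19.7% of genes in the KCTD comparison, for 2.99%, 17.9% and 28.8% in that of slc5a7a, and for 0%, 7.46% and 18.2% in that of tubb5 with sox4a. With limma, planted shifts of 1, 2 and 4 log2 units were recovered for 46.3%, 86.6% and 100% of genes, for 46.3%, 77.6% and 95.5%, and for 23.9%, 64.2% and 97%. False calls were 10, 10 and 1 with limma and 0, 1 and 0 with edgeR. The recovered shares of edgeR and limma cannot be set against each other. The folds multiplied class sums of genes that passed filterByExpr. The shifts were added to means of log2(CPM + 1) of genes found in 10% of cells. The planned test thus had little power here, and an absent call is no evidence of equal expression.

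Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.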

Results

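Of 1140 sorted cells, 1056 (92.6%) passed the filter: 345 of 372 in batch 1, 357 of 384 in batch 2 and 354 of 384 in batch 3. The median over these 1056 wells was 739303 counts. Median counts per well were 604555, 891235 and 904138 in batches 1 to 3, and median genes 3732, 3798 and 3535.5. After near-identical wells were merged 1054 cells remained. In each merged pair the wells differed by little more than sampling noise and were counted as 1 cell.

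Most cells carried the reporter's gene and neuronal genes. gng8, a G protein gamma subunit whose promoter drives the reporter, reached 50 CPM in 83.4 ± 14.3% of cells (mean ± SD of 3 batches, n = 3, as for all shares here). elavl3, an RNA-binding protein of neurons, did so in 88.4 ± 4.60%. kctd12.1 and kctd8, GABA-B receptor auxiliary subunits known from the dorsal habenula, did so in 68.4 ± 9.32% and 65.8 ± 9.36%, and kctd12.2 in 25.7 ± 12.3%. The sort was for the reporter, so these shares describe sorted cells and not the habenula.

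Peptide and transmitter genes divided the cells further. tac3a, the precursor of neurokinin B, reached 50 CPM in 41.8 ± 4.09% of cells and sst1.1, a somatostatin precursor, in 30 ± 1.06%. slc5a7a, the choline transporter of cholinergic neurons, did so in 27.8 ± 7.87%, and gpr151, an orphan receptor of the habenula, in 41.4 ± 13.3%. pou4f1, a transcription factor of habenular neurons, did so in 13.2 ± 4.43%. Rarer were kiss1, a kisspeptin precursor known from the ventral habenula (2.38 ± 1.84%), and aoc1, a marker of the same region (1.05 ± 0.716%).

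Clustering gave 14 clusters, described here by the share of cells with a gene at 50 CPM or more. tac3a was found in 100% of the 188 cells of cluster 1, against 29.1% of all other cells, with adcyap1b (98.9% against 43.8%) and tacr3l, a receptor for tachykinins (94.1% against 22.6%). cckb, a cholecystokinin precursor, was found in 97.7% of the 133 cells of cluster 2. wnt7aa, a Wnt ligand, was found in 66.7% of the 102 cells of cluster 4, against 5.04% elsewhere. Other clusters were led by tac3a with zic2b and kctd12.2 (cluster 5, 93 cells), spa17 with sst1.1 (cluster 6, 84 cells), pnoca, sst1.1 and foxa1 (cluster 7, 69 cells), and onecut1 with tac3a (cluster 10, 42 cells). Cluster 14 (17 cells) had kiss1 in 88.2% of cells, against 0.964% elsewhere, and aoc1 in 58.8%, against 0.096%.

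Some clusters carried genes of other states or tissues. Cluster 11 (40 cells) was led by tubb5 (97.5% of cells) and sox4a (72.5%), genes of young neurons, with islr2 in 95%. Cluster 9 (53 cells) held gad2, a GABA synthesis enzyme, in 24.5% of cells against 0.1% elsewhere, and slc32a1, the vesicular GABA transporter, in 26.4% against 0.3%. Cluster 12 (37 cells) was olfactory sensory neuron-like, with calb2a in 100% of cells against 0.098% elsewhere, and was left out of the gates. Cluster 8 (62 cells) was led by fat2, a large cadherin, in 96.8% of cells against 1.11% elsewhere, with neurod1, reln and gabra6b, and stayed unnamed.

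Several clusters were unequally spread over the batches. Cluster 3, with tac3a, tgfbi and kctd4, held 1.45%, 3.09% and 25.2% of the cells of batches 1, 2 and 3, and cluster 8 held 0.87%, 0% and 16.7%. Cluster 12 held 3.77%, 6.74% and 0%. With each batch taken as 1 pool of fish no test between batches was made, and a cluster found mostly in 1 batch may be that pool and not a type.

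**Figure D1:**
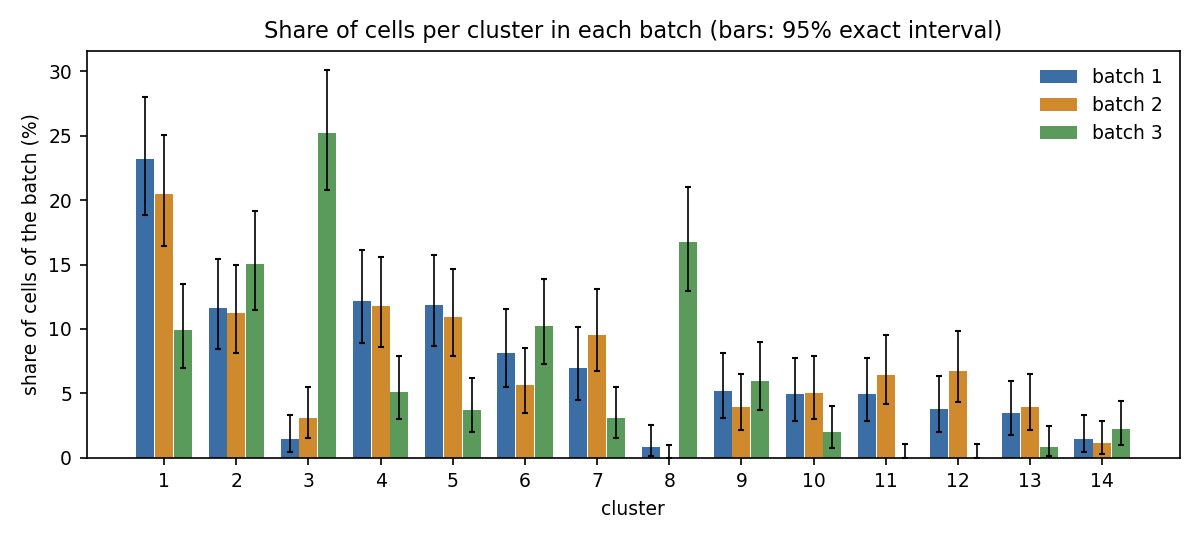
Share of the cells of each batch (vertical axis) in each of the 14 clusters (horizontal axis). Bars give 95% exact binomial intervals, which cover counting error only.

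The planned comparison set cells with kctd12.1 but not kctd8 at 50 CPM against cells with the reverse. wnt7aa and fstl1b rose in the kctd12.1-only cells by the planned edgeR test. wnt7aa stood at 229 ± 66.4 CPM against 0.01 CPM (n = 3 batches, adjusted p = 0.0462), and 20.5 ± 11.8% of kctd12.1-only cells against 0% reached 50 CPM. fstl1b, a secreted glycoprotein related to follistatin, stood at 77.8 ± 27.9 against 1.12 ± 0.31 CPM (log2 fold 6.0, SE 0.564, adjusted p = 0.0462). These were the only calls among 18116 genes, 949 of which had an unadjusted p under 0.05 in edgeR. limma called 121 genes and DESeq2 965 (542 higher, 423 lower), beside the 470 to 567 that DESeq2 called with shuffled classes. The edgeR calls fell to 0 with RLE size factors, with only the 2 compared classes fitted, without any 1 batch, and at gates of 10 or 200 CPM.

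The limma test, added after seeing the data, called 121 of 9411 genes, 101 higher and 20 lower in kctd12.1-only cells (1396 at unadjusted p under 0.05). All 121 had the same direction in edgeR, where 78 had an unadjusted p under 0.05, and both edgeR calls were among them. The count was 36 with no block, 1 to 33 without 1 batch and 0 at a gate of 10 CPM. The largest rise was of cckb: 768 ± 117 against 49.3 ± 5.25 CPM, found in 54.7 ± 1.86% of cells against 10.4 ± 0.16% (log2 difference 4.57, SE 0.227, n = 3, adjusted p = 2.98e-05). The tetraspanins tspan18b (4.03, SE 0.387, adjusted p = 0.00403) and tspan18a (3.69, SE 0.402, adjusted p = 0.00672) rose as well. So did slc35g2a (3.75, SE 0.519), the carbonic anhydrase family genes ca16b (3.63, SE 0.635) and ca10a (3.19, SE 0.313), the neuronal membrane protein gene ctxn1 (3.43, SE 0.426), and akap6, a kinase anchor (2.92, SE 0.400).

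Of the 20 genes lower in kctd12.1-only cells tac3a had the largest difference. tac3a fell from the kctd8-only to the kctd12.1-only cells, with 1876 ± 734 against 645 ± 67.1 CPM and 61.2 ± 11.6% against 25.3 ± 3.07% of cells (log2 difference -4.10, SE 0.608, n = 3, adjusted p = 0.0153). tacr3l fell likewise (-3.22, SE 0.559, adjusted p = 0.0287), as did slc5a7a (-2.60, SE 0.444, adjusted p = 0.0260) and agrn, the synapse organiser agrin (-2.65, SE 0.479, adjusted p = 0.0333). Also lower were the matrix protein gene frem2b (-3.38, SE 0.659), plekhg5 (-2.43, SE 0.378), shroom2 (-2.30, SE 0.434), the cyclic GMP-dependent kinase gene prkg2 (-2.07, SE 0.374), and ttna (-1.95, SE 0.352).

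**Figure D2:**
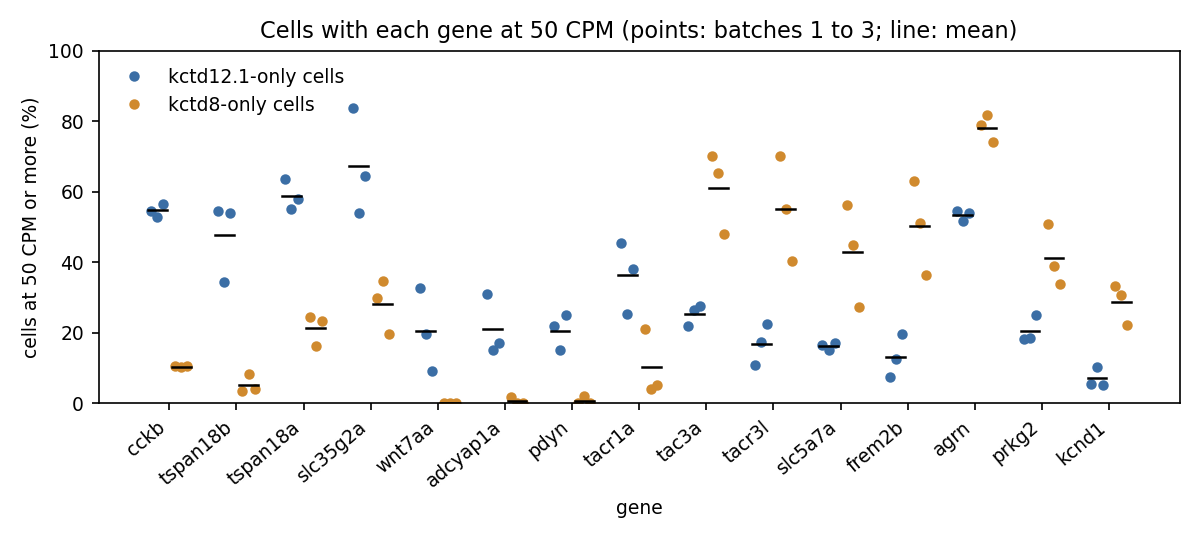
Share of cells with each of 15 genes at 50 CPM or more (vertical axis, %) in kctd12.1-only (blue) and kctd8-only (orange) cells. Points are batches 1 to 3 and lines their mean.

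By list, limma called 4 of 18 neuropeptide and granin genes. cckb, pdyn (1.65, SE 0.161, adjusted p = 0.00403) and adcyap1a (2.09, SE 0.276, adjusted p = 0.0116) rose, tac3a fell, and 14 did not pass. Adjusted over the list alone, 5 of all 18 were higher and 1 lower. pdyn encodes the dynorphin precursor and adcyap1a that of PACAP, and they were found in 20.6% against 0.68% and in 21.0% against 0.58% of cells of these classes. Cells with both KCTD genes were not part of the contrast. Among those not passing were sst1.1 (0.93, adjusted p = 0.630) and adcyap1b (0.06, adjusted p = 0.963). Of 10 peptide and amine receptors, tacr1a, which binds substance P, rose (2.14, SE 0.299, adjusted p = 0.0133), tacr3l fell and 8 did not pass (of all 10, 2 higher and 2 lower adjusted over the list alone).

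Of 53 axon guidance genes in limma, plxna4 (2.24, SE 0.324, adjusted p = 0.0148) and plxna1b (0.61, SE 0.115, adjusted p = 0.0354), receptors of semaphorin signals, rose. sema3b, a secreted semaphorin, fell (-1.64, SE 0.326, adjusted p = 0.0488), and 50 did not pass (of all 53, 7 higher and 11 lower adjusted over the list alone). In camera on the edgeR fit the 85 tested guidance genes were lower as a list (adjusted p = 0.0284, fry 0.0388; adjusted p = 0.131 with an estimated correlation). With no block 2 lists passed and with camera on the limma fit 0 of 23, smallest adjusted p = 0.0857. fry on the limma fit called neuropeptides and granins (adjusted p = 0.00677) and 4 cell cycle genes (adjusted p = 0.0317), both up. The other 31 lists had adjusted p from 0.113 to 0.99 in camera. On the edgeR fit fry also called the oligodendrocyte lineage list (down) and the pallial and subpallial neuron list (up), both at adjusted p = 0.0491.

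In Wnt signalling limma called wnt7aa (2.05, SE 0.363, adjusted p = 0.0313) and axin1, a scaffold that restrains beta-catenin (1.48, SE 0.282, adjusted p = 0.0401), both up, and 16 did not pass (of all 18, 2 higher and 3 lower adjusted over the list alone). Single members rose among 5 glutamatergic, 30 synaptic vesicle, 28 immediate early and 24 heat shock genes: slc17a7b, a vesicular glutamate transporter (1.12, SE 0.184, adjusted p = 0.0223), syn2b, a synapsin (2.98, SE 0.467, adjusted p = 0.0175), sik1, an activity-induced kinase (2.19, SE 0.373, adjusted p = 0.0260), and hspe1, a mitochondrial chaperonin (1.70, SE 0.232, adjusted p = 0.0116). Adjusted over the list alone these lists had 1, 2, 4 and 1 higher and 0, 0, 2 and 0 lower. Of 30 voltage-gated channels 1 fell, the A-type potassium channel kcnd1 (-2.06, SE 0.274, adjusted p = 0.0116). No member of the 42 transcription factors passed (5 higher and 5 lower adjusted over the list alone), with prox1a at -3.23 (adjusted p = 0.0962). Of 8 dorsal habenula genes tac3a and slc5a7a fell and 6 did not pass, among them gpr151 (0.06, adjusted p = 0.969). No member of the other tested lists passed, nicotinic, KCTD, Notch, cell cycle and immature neuron genes included.

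The gate genes themselves stood at 2928 ± 486 against 1.72 ± 0.577 CPM (kctd12.1) and 22.3 ± 1.23 against 897 ± 150 CPM (kctd8). gng8 stood at 1062 ± 115 against 982 ± 429 CPM and reached 50 CPM in 94.3 ± 1.8% against 77.0 ± 18.4% of cells (mean ± SD, n = 3), or 205 of 218 against 136 of 183 cells. Its difference did not pass in limma (1.45, SE 0.809, adjusted p = 0.456), which does not show equal levels. The classes are uneven mixtures of clusters: 33.9% of the 218 kctd12.1-only cells were in cluster 2 and 22.5% in cluster 4, while 32.8% of the 183 kctd8-only cells were in cluster 1, 0 in cluster 2 and 17 cells in cluster 8. kctd8 counts were widespread, with 23.5% of cells between 25 and 100 CPM and 18.9% of the olfactory sensory neuron-like cells at 50 CPM, so its gate divides a continuous range.

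Shares of the gates were 21.4 ± 4.82% kctd12.1-only, 17.9 ± 3.59% kctd8-only, 49.7 ± 12.7% both and 10.9 ± 8.32% neither, over 1017 cells (n = 3). kctd12.1 and kctd8 were found together 1.03 times as often as independent detection gives (1.0 to 1.08 over batches). Cells of cluster 8, nearly all of batch 3, were included in that count. Median kctd8 in kctd12.1-only cells was 21.9 CPM and median kctd12.1 in kctd8-only cells 0 CPM.

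The comparison of 282 slc5a7a-positive with 574 slc5a7a-negative dorsal-marker cells was chosen after seeing the data. No gene passed in edgeR (0 of 18005, 853 at unadjusted p under 0.05) or limma (0 of 9409, 962 unadjusted), while DESeq2 called 744 (127 higher, 617 lower). tac3a had the widest gap, with 2465 ± 774 against 551 ± 223 CPM and 85.2 ± 7.26% against 26.7 ± 9.25% of cells (log2 difference 6.42, SE 0.938, n = 3 batches, limma adjusted p = 0.125). prox1a, a homeobox transcription factor, was found in 64.1% against 21.5% of cells (4.25, adjusted p = 0.147), and cckb in 19.2% against 45.5% (-2.81, adjusted p = 0.172). The smallest limma p-values were those of grid1a, a delta glutamate receptor (-2.09), and plxna4 (-1.95), both at adjusted p = 0.0666.

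The choline transporter itself stood at 803 ± 59.4 against 0.446 CPM. The 282 positive cells lay mainly in cluster 1 (42.6%), cluster 5 (17.4%) and cluster 3 (16%), and none in clusters 4 and 7. Cluster 11, led by tubb5 and sox4a, held 1 positive cell (0.355%) against 33 negative cells (5.75%). Other values in limma were kcnd1 (2.51, adjusted p = 0.145), gria1b, an AMPA receptor subunit (2.21, adjusted p = 0.125), nrp1a, a semaphorin co-receptor (-2.05, adjusted p = 0.125), adcyap1a (-1.39, adjusted p = 0.125), and ache, acetylcholinesterase (-1.20, adjusted p = 0.305). Adjusted over the list alone in limma, 3 of 18 peptide genes were higher and 4 lower, 6 of 53 guidance genes higher and 7 lower, 3 of 42 transcription factors higher, and 4 of 25 immature neuron genes lower. A gate at 200 CPM gave 47 limma calls, 11 higher and 36 lower.

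In camera on the edgeR fit 4 of 30 lists were lower in slc5a7a-positive cells, and none with an estimated correlation. They were immature neuron genes (adjusted p = 2.79e-05; adjusted p = 0.14 with an estimated correlation), voltage-gated channels (adjusted p = 0.000597; 0.336 estimated), nicotinic receptor subunits (adjusted p = 0.0378; 0.423 estimated) and cell cycle genes (adjusted p = 0.0378; 0.702 estimated). The lower immature neuron list may come from the uneven share of cluster 11, and the test was not repeated without that cluster. The other 26 lists had adjusted p from 0.1 to 0.96. In camera on the limma fit 2 of 23 lists passed: immature neuron genes down and transcription factors up (adjusted p = 0.0457), and 0 with an estimated correlation (0.753 for each). fry on the edgeR fit called 4 of 30 lists, all down. They were immature neuron genes (adjusted p = 0.00789), and nicotinic receptor subunits, voltage-gated channels and axon guidance (adjusted p = 0.047 each). fry on the limma fit called 0 of 23, smallest adjusted p = 0.253. The median log2 fold of all genes was -0.108 in edgeR and -0.08 with RLE size factors.

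A further comparison, also chosen after seeing the data, set 55 cells with tubb5 and sox4a, genes of young neurons, against 725 cells with neither. Only batches 1 and 2 held enough positive cells (30 and 20; 5 in batch 3), so n = 2. Among the 10 largest rises in limma were islr2, a membrane protein of growing axons, at 2483 ± 148 against 433 ± 173 CPM (log2 difference 5.55, SE 0.568, adjusted p = 0.00337), marcksb at 1342 ± 19.5 against 280 ± 31.1 CPM (5.25, SE 0.330, adjusted p = 0.00282), stmn1b, a tubulin-binding stathmin (5.25, adjusted p = 0.00325), and robo1, a Slit receptor (4.41, SE 0.467, adjusted p = 0.00379). aldocb, an aldolase, fell (-5.12, SE 0.689, adjusted p = 0.00758), as did tac3a (-4.41, SE 0.542, adjusted p = 0.00584), scg2b, a granin (-4.46, SE 0.691, adjusted p = 0.0115), and the activity-induced transcription factors egr4 (-4.74, SE 0.386, adjusted p = 0.00282) and npas4a (-4.46, SE 0.774, adjusted p = 0.0159).

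limma called 1024 of 9411 genes, 722 higher and 302 lower (2559 at unadjusted p under 0.05), and 350 with no block. edgeR called 0 of 19216 (2480 unadjusted), and DESeq2 3381 (1084 higher, 2297 lower). Of the limma calls 1022 had the same direction in edgeR, where 719 had an unadjusted p under 0.05. The median log2 fold of all genes was -0.673 in edgeR, -0.513 with RLE size factors and -0.016 in limma. 52.7% of the positive cells were in cluster 11, which tubb5 and sox4a lead.

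By list, 15 of 23 immature neuron genes rose in limma, none fell and 8 did not pass (of all 23, 19 higher and 1 lower adjusted over the list alone, and likewise over all members in the brackets that follow). Examples were gap43, a growth cone protein (3.51, SE 0.243, adjusted p = 0.00282), tmsb (4.41), dpysl3 (3.42) and hmgn2 (3.28). The gate genes come from this list, so its rise is partly built into the choice. Of 21 pan-neuronal genes 6 rose and 1 fell (9 and 2 adjusted over the list alone), with elavl4 (2.68), maptb (2.25) and snap25b (2.76) among those that rose. The pan-neuronal list shares elavl3, stmn1b, stmn2a, stmn2b and gap43 with the immature neuron list, so the 2 rises are not fully separate results. elavl4, maptb and snap25b are not among the shared genes. Of 53 guidance genes 10 rose and 2 fell (14 and 5), and 41 did not pass, with cntn2 (3.28) and robo1 higher (limma camera adjusted p = 0.308 for the list).

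Of 18 neuropeptide and granin genes 0 rose, 6 fell and 12 did not pass (0 and 8 adjusted over the list alone), including sst1.1 (-2.01) and the processing enzyme gene cpe (-2.08). Of 28 immediate early genes 9 fell, 0 rose and 19 did not pass (0 and 10), including fosab (-4.18), gadd45ba (-3.64) and sik1 (-2.88). Of 10 receptors 2 fell, and of 30 synaptic vesicle genes 1 rose, 3 fell and 26 did not pass (2 and 5), with these lower: cplx1, a complexin (-3.21), and rims1a, an active zone protein (-3.01). Of 10 dorsal habenula genes 5 fell, 0 rose and 5 did not pass (0 and 6), including gpr151 (-2.14), slc5a7a (-2.80) and kctd12.1 (-1.44).

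Of 42 transcription factors 7 rose and 1 fell in limma (14 and 2 adjusted over the list alone), with irx3a (2.34), foxp2 (2.42) and zfhx4 (2.89) higher. Of 12 Notch and progenitor genes 3 rose: hmga1a, a chromatin protein (3.52), insm1a, a factor of neuronal differentiation (2.95), and vim, vimentin (1.39). Heat shock and unfolded protein genes went both ways, 5 up and 4 down (9 and 7), with hsp90b1 (3.38) higher and hsp70l (-2.08) lower.

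In camera on the edgeR fit 7 of 32 lists passed, and none with an estimated correlation. Higher were immature neuron genes (adjusted p = 5.59e-17; adjusted p = 0.47 with an estimated correlation), pan-neuronal genes (7.57e-05; 0.47), transcription factors (0.000273; 0.47) and Notch and progenitor genes (0.00359; 0.47). Lower were neuropeptides and granins (0.0277; 0.484), peptide and amine receptors (0.00359; 0.47) and immediate early genes (7.57e-05; 0.508). For transcription factors and for Notch genes the mean log2 fold (-0.167 and -1.09) had the opposite sign to the test. The other 25 lists had adjusted p from 0.0738 to 0.898, fry called 9 lists on the edgeR fit and 9 of 23 on the limma fit, and camera on the limma fit 7 of 23, with 0 at an estimated correlation.

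The remaining planned comparisons had too few cells for any test. 7 cells passed the ventral-marker gate (0, 2 and 5 per batch), and 6 were positive for cxcr4b, a chemokine receptor (3, 2 and 1). chata, choline acetyltransferase, had no counts in any of 1054 cells. chata is a gene of the tables, so the annotation used for counting held it. Whether its gene model would catch the reads is not given in the sources used here. The lack of counts therefore does not show that chata was absent. slc18a3a, a vesicular acetylcholine transporter, reached 50 CPM in 0.097 ± 0.167% of cells. The cholinergic gate needed at least 2 of chata, slc18a3b and slc5a7a at 50 CPM, and no cell passed it. No level of slc18a3b is reported here. aoc1 or kiss1 reached 50 CPM in 2.52 ± 1.68% of cells, 26 in all.

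Some stress, activity and clock genes stood at different levels in the 3 batches. dnajb1b, a co-chaperone, reached 50 CPM in 45.0%, 81.0% and 56.5% of cells of batches 1, 2 and 3 (329, 332 and 294 cells, those of the gates without cluster 8), and the endoplasmic reticulum chaperone hspa5 in 72.6%, 94.3% and 67.3%. The mean of hsp70l was 1509, 15889 and 16272 CPM, and that of the constitutive chaperone hspa8 was 5198, 6284 and 5867 CPM. hspa8 was found in 100%, 99.7% and 99.3% of cells. Of the immediate early genes npas4a was found in 74.8%, 56.6% and 87.4% of cells, fosab in 71.7%, 60.2% and 82.3%, and egr4 in 82.1%, 67.5% and 67.7%. egr1 was found in 35.6%, 35.8% and 32.7% and nr4a1 in 12%, 7.83% and 9.86%. The clock genes per2, a light-induced repressor, and nr1d1, a nuclear receptor of the clock, were found in 77.2%, 59.3% and 28.6% and in 26.1%, 5.12% and 13.9%. Each batch was taken as 1 pool of fish, so no test was made.

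**Figure D3:**
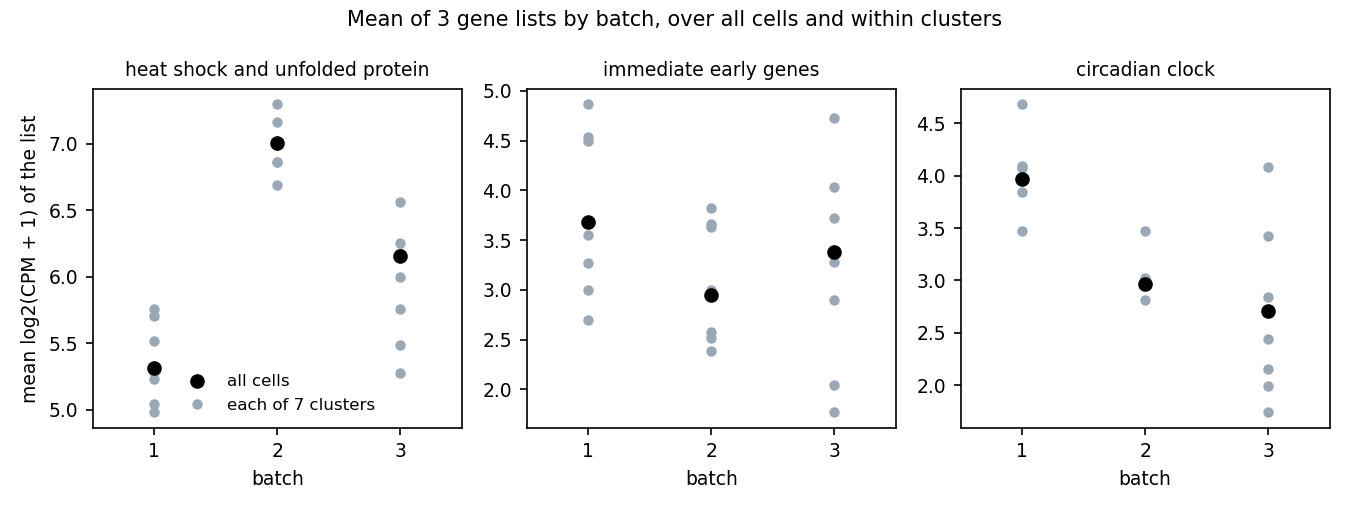
Mean log2(CPM + 1) of the genes of 3 lists (vertical axis) in batches 1 to 3 (horizontal axis). Black points are all cells of the gates outside cluster 8 and grey points each of 7 clusters with at least 10 cells in every batch.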

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

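The rule for plates that stand apart was fixed before the data were examined, and no test in this part was chosen after the result was seen. Of 18 groups of 4 plates, 2 held a plate that stood apart from the rest, and chance alone gives about 1 in 20 such groups. Plate 4 of batch 1 had a median of 505512 counts per cell, against 621662 to 637212 on the other plates of its batch. Its cells were kept, since CPM divide by the depth of each cell. On plate 6 of batch 2, 16.3% of cells had neither kctd12.1 nor kctd8 at 50 CPM, against 10.6% to 11.4% on the other plates. These shares are over all filtered cells, including those of the olfactory sensory neuron-like cluster, which held 9.30% of cells on plate 6 against 4.55% to 7.95% on the others. Cells of that cluster were left out of the KCTD fit, and the remaining cells with neither gene entered only its estimate of spread. The cause of either plate's value was not tested.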

How the results depend on the processing

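The limma fits, the fits on genes found in 10% of cells, those without the fat2 cluster, those on cells with gng8 at 50 CPM and the whole comparisons of slc5a7a and of tubb5 with sox4a were chosen after seeing the data, as were their tests. For the KCTD classes the 2 edgeR calls became 1 with no replicate block, 965 with DESeq2, and 0 with RLE size factors, with no filter on low counts, with only the 2 classes fitted, without any 1 batch (0 to 0), with gates at 10 or 200 CPM, with all clusters, without the fat2 cluster or with gng8 at 50 CPM. fstl1b reversed at a gate of 10 CPM (log2 fold -1.08, adjusted p = 0.815), where the median of all genes was -1.079 and the cause was not tested. The 121 limma calls became 36 with no block, 1 to 33 without 1 batch, 0 at a gate of 10 CPM and 219 with all clusters. For slc5a7a the edgeR count of 0 became 744 with DESeq2, and the limma count of 0 became 47 at a gate of 200 CPM and 2 with all clusters. For tubb5 with sox4a the edgeR count of 0 became 11 with no block, 3381 with DESeq2, 1 on genes found in 10% of cells and 1 without the fat2 cluster. Its 1024 limma calls became 350 with no block. Leaving out batch 1 or 2 there would leave 1 positive sample and was not run. Lists called between the KCTD classes (1) became 0 with an estimated correlation, 2 with no block, 3 with fry, 0 to 3 without 1 batch and 0 with camera in limma. For slc5a7a (4) they became 0 with an estimated correlation, 5 with no block, 2 to 5 without 1 batch and 2 with camera in limma, and for tubb5 with sox4a (7) 0 with an estimated correlation. Beyond these counts and the genes within them, leaving out the block changed no other call. Of 372 values of 31 limma-named genes between the KCTD classes 238 kept their call and 134 became weaker, and of 570 values of 57 genes for tubb5 with sox4a 507 and 63, none reversed. The share of cells passing, 92.6%, became 93.7% with 500 genes and 91.8% with 2000. At gates of 10 and 200 CPM the kctd12.1-only share of 21.4% became 3.26% and 32.7%, the kctd8-only share of 17.9% became 26.5% and 13.2%, and both, 49.7%, became 68.9% and 37.0%. Neither, 10.9%, became 1.36% and 17.1%, and 6.17% without batch 3. The 14 clusters became 10 at resolution 0.5, 22 at resolution 2.0, 13 and 12 with cell filters of 500 and 2000 genes, and 15 with genes z-scored over all cells. The ventral-marker, cxcr4b and cholinergic comparisons had too few cells at every setting and were not run.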

Other observations

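The granule cell list below was written after the leading genes of cluster 8 were seen but before its test was run, while the other tests of this part were chosen only after the result was seen. Pairs of peptide and transporter genes, chosen after their values were seen, differed in how often they were found together. tac3a and cckb were found together 0.493 times as often as independent detection gives (0.309 to 0.617 over batches, n = 3), in 7.29 ± 3.23% of cells. tac3a and slc5a7a were together 1.96 times as often (1.82 to 2.09), in 24.7 ± 8.66% of cells, cckb with adcyap1a 2.88 times (2.67 to 3.13), and tac3a with adcyap1b 1.43 times (1.32 to 1.53). Less steady over batches were slc5a7a with cckb (0.574, 0.252 to 0.895), kctd12.2 with slc5a7a (1.40, 1.18 to 1.81) and tac3a with sst1.1 (1.2, 0.956 to 1.41). sst1.1 and pnoca, the precursor of nociceptin, were together 2.61 times as often (2.57 to 2.64). Cells of cluster 8, nearly all of batch 3, were counted in these pairs. In its 62 cells tac3a and cckb were found in 0%, sst1.1 in 3.23% and slc5a7a in 1.61%. Cells that lack both genes of a pair raise its ratio, so values of batch 3 may be raised. The pairs were not recounted without cluster 8.

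Small clusters carried further peptides and receptors. Cluster 13 (29 cells) had pyya, a peptide YY precursor, in 82.8% of cells against 0.39% elsewhere, with cbln1, a synapse organiser, in 86.2% and the dopamine receptor gene drd4a in 58.6%. Cluster 7 had pnoca in 92.8% against 9.34% and the forkhead factor gene foxa1 in 79.7% against 1.32%. In cluster 9, gad1b stood beside gad2 in 24.5% of cells against 0.2%, and junba, an immediate early gene, in 60.4% against 4.90%. The choline transporter gene slc5a7a was found in 65.4% of cluster 1 and 66.7% of cluster 10.

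Cluster 8, found almost only in batch 3, may be neurons of another brain region or habenular cells changed by handling. A list of 16 cerebellar granule cell genes had a higher median difference in the cluster than 99.99% of 10000 random lists, but that median was only 0.318 log2 units, 7 of the 16 genes had a difference of 1 or more and 5 were below 0, and 8 of the 16 were already in the fixed lists scored for every cluster. barhl1b, a factor of granule cell progenitors, was found in 54.8% against 0.628% of other cells and cbln12 in 69.4% against 4.71%, but etv1 in 4.84% against 69.0%. gabra6a (1.61% against 0%) and pax6a (0% against 0.733%) were rare in both. gng8 reached 50 CPM in 1.61% of the cluster's cells (exact interval 0.041% to 8.66%), against 80.3% of the other cells of batch 3 (75.3% to 84.7%). The intervals do not overlap, but they cover only counting error over cells mostly of batch 3. By the rule set for it after the result was seen, the gap counts against habenular cells changed by handling. It rests on 1 gene, and whether handling can lower gng8 was not tested. gng8 also reached 50 CPM in 97.3% of the olfactory sensory neuron-like cells, so it does not mark the habenula alone. The gap therefore does not show which region the cells came from. Whether these cells carried the reporter or were sorted without it was not tested.

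Heat shock, immediate early and clock genes could differ between batches because of cell mixtures, depth or handling. For the heat shock list the median difference within clusters was 1.036 times that over all cells, and batch 2 was highest in 7 of 7 clusters, which speaks against different mixtures. Clock genes were highest in batch 1 in 7 of 7 clusters, and the mean of immediate early genes in 6 of 7, although npas4a and fosab were highest in batch 3. For the heat shock list the gap between batches 2 and 3, which had similar depth, was 0.504 of the largest gap between batches. That only just passed the level set for counting against depth, and within clusters the value ran from 0.426 to 1.0. The gaps were -0.426 beside 0.732 log2 units for immediate early genes and 0.258 beside 1.25 for clock genes. An effect of depth therefore stays open. With 1 pool per batch, handling and time of day cannot be told apart from the batch itself.

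kctd8 counts in olfactory sensory neuron-like cells could be carryover from other wells or reads of another gene or of unspliced RNA. Whether these cells express kctd8 themselves was not tested. Their median kctd8 was 14.3 CPM while their median kctd12.1, the more abundant gene elsewhere, was 0, which speaks against carryover. In the other cells 98.6% had kctd8 at 5 CPM or more, so reads of another gene or of unspliced RNA remain possible. The classes based on kctd8 should therefore be read as high against low.

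For the KCTD classes, 10 splits of the 6 class sums cannot give a share under 0.05. Most of the other splits put both classes of a batch on the same side, so the splits that keep the pairing are fewer still. The real grouping gave 2 calls in edgeR and 121 in limma, the highest other split 0 in each, and 1 of 10 splits, the real one, had as many. For slc5a7a all 10 of 10 splits gave 0 in edgeR and likewise 10 of 10 in limma.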
